A study of Mus musculus with 12 samples.

How the data were processed

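Lung DC were sorted from C57BL/6 male mice 16 h after 100 ng of lipopolysaccharide and 100 ug of ovalbumin were given into the airways in 50 ul of buffer. For each biological replicate 20 mice were used, and whether populations of the same replicate number came from the same mice is not given in the sources used here. The samples had a sort purity of over 93% by the labels and 50 ng of RNA amplified and biotin labelled. The platform was the Affymetrix mouse genome array named in the labels, with 3 arrays in each of 4 populations. The deposited values are linear intensity values made with MAS5, as the submitters' processing notes state, and the authors had scaled each array so that its 2% trimmed mean was 500.003 on all 12. The MAS5 version, the target and the detection calls are not given in the sources used here, so no probe set could be called absent and a filter on signal stood in for such calls. No array was rescaled or left out.

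Of 45101 probe sets, 64 were controls and were left out. A probe set was kept where its signal exceeded the median of its array in at least 3 of 12 arrays, which left 25138. Gene symbols came from the platform annotation. Among all probe sets 34958 carried 1 symbol, 932 several and 9160 none, and only those with 1 symbol were assigned to a gene. The kept probe set of the highest mean stood for its gene, a choice that mattered for 5645 genes with several, and 10929 genes were tested. A pseudocount of 50.0003, which is 10% of the trimmed mean, was added before taking log2.

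A mean per population was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, with 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, by two-sided tests, in each of 7 comparisons. All adjusted p values of genes come from limma, and all adjusted p values of lists from camera within limma. A gene was specific to a population when it was called in the same direction against all 3 others. In the 7 comparisons, 32 gene lists were examined. List results are given for the first 4, since only markers and counts were planned for the other pairs. Not every list is described there, and some of the lists left out were called. Of the lists, 25 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the lists of a comparison. Figures were drawn with matplotlib 3.10.9.

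The comparisons, tests, filter, lists, processing alternatives and the rule for naming genes were fixed before the data were examined. The rule named, for each of the first 4 comparisons, the 6 genes with the largest rise and the 6 with the largest fall among called genes whose arrays did not overlap between the sides, so that every array of one side lay beyond every array of the other. It also named the sort and study markers, up to 4 called members of a list with the largest differences, and for each population the 5 highest and 3 lowest of its specific genes. The alternatives were quantile normalization, median centring, a smaller and a larger pseudocount, no filter and a stricter one at the 75th percentile, the mean of a gene's probe sets, every probe set on its own, only the arrays compared, no intensity trend, a 2-fold requirement, replicate number as a block, and leaving out each array in turn. On simulated data, with 200 of 10929 genes changed between arrays of a real comparison, 72% of 2-fold and 98% of 4-fold changes were recovered, and 7 of 177 calls were false. In the unchanged comparison limma made 0 calls. The simulated noise was independent between genes and arrays, which real arrays need not be, so these rates may not hold for the real comparisons.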

Results

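Gene expression was measured in 4 dendritic cell (DC) populations sorted from the lungs of C57BL/6 mice after lipopolysaccharide, a bacterial cell wall component that drives inflammation, and ovalbumin, a foreign protein, had been given into the airways. The populations were CD103+ conventional DC (CD103+ cDC), CD11bhi CD14lo conventional DC (CD14lo cDC), CD11bhi CD14hi monocyte-derived DC (CD14hi moDC) and CD11bhi Ly6Chi monocyte-derived DC (Ly6Chi moDC, inf.moDCs in the labels). Each population had 3 arrays, 12 in all, and this number limits the precision. Signals are MAS5 intensities in arbitrary units, given as mean ± SD of 3 arrays. A log2 difference is given with its SE from the limma model (3 arrays per population), on signals raised by a pseudocount, so folds of dim genes are understated. The median signal of an array ran from 72.4 to 109. Correlations between arrays of the same population, taken across genes, ran from 0.973 to 0.983, although genes are not independent replicates. The 3' to 5' signal ratio of the Gapdh control probe sets, a measure of RNA quality, was 2.74 ± 0.91 in CD103+ cDC, 1.85 ± 0.39 in CD14lo cDC, 1.68 ± 0.14 in CD14hi moDC and 1.66 ± 0.22 in Ly6Chi moDC (SD, n = 3). It ran from 1.48 to 3.27 over single arrays, and the signal of the bioB hybridization control from 2699 to 8366. The same ratio of beta-actin differed little, with means of 1.04 ± 0.08, 1.00 ± 0.01, 1.03 ± 0.01 and 1.03 ± 0.03 in the same order (SD, n = 3).

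The first principal component held 57.9% of the variance and placed CD103+ cDC between -69.3 and -61.7, CD14lo cDC between -8.66 and -4.29, CD14hi moDC between 18.3 and 22.3, and Ly6Chi moDC between 50.4 and 52.0. Across genes, the mean correlation of CD14lo cDC arrays was 0.931 with CD14hi moDC arrays, 0.909 with Ly6Chi moDC arrays and 0.904 with CD103+ cDC arrays. The lowest mean correlation, 0.800, was between CD103+ cDC and Ly6Chi moDC. Of 10929 genes tested, the number called between 2 populations ran from 1780 for CD14hi moDC against CD14lo cDC to 5191 for CD103+ cDC against Ly6Chi moDC.

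The first comparison asked which genes part the conventional from the monocyte-derived populations, taking the mean of both populations on each side. Genes of conventional DC identity were higher in the cDC: Flt3, the receptor for a growth factor on which conventional DC depend, was 11.6-fold higher (log2 difference 3.53 ± 0.12, adjusted p = 3.8e-13). The monocyte-derived populations carried far more message for chemokines that attract monocytes, Ccl12, Ccl7 and Ccl2, which were 56.2-fold, 38.0-fold and 35.6-fold lower in the cDC. They also carried more of C1qa and C1qc, subunits of the complement component that starts the classical pathway, which were 30.4-fold and 29.8-fold lower in the cDC, and of the membrane protein gene Ms4a7, 28.5-fold lower. In all, 2273 genes were higher and 2260 lower in the cDC, which is 41.5% of the genes tested, and 561 and 623 of them differed by at least 2-fold. A comparison of such means can also be called when a single population differs. For 1275 of the 10929 genes tested, the arrays of the sides did not overlap. Besides Flt3, the largest differences on the cDC side were in Itgae, which encodes the sort marker CD103 (22.9-fold), Septin3 (16.6-fold), the tight junction gene Cldn1 (15.2-fold), the adhesion gene Epcam (9.69-fold) and Sema4f (8.85-fold). Of these, Itgae, Septin3, Cldn1, Epcam and Sema4f were most abundant in CD103+ cDC, with Itgae at 15178 ± 2597 there against 855 ± 345 in CD14lo cDC.

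Lists are given with the camera test at its preset correlation, and where that call was lost with a correlation estimated from the arrays, the second value is given too. The conventional DC core list holds Dpp4, the monocyte and macrophage core Cd14 and C5ar1, the complement list Itgam and C5ar1, the pattern recognition receptor list Cd14, the CD11b+ DC list Itgam and the CD103+ DC list Itgae, which are sort or study markers, so those members are not independent evidence. Among 13 genes of the conventional DC core list, 12 were higher in the cDC, as many when adjusted over the list alone (camera adjusted p = 1.3e-12). Kit was 8.18-fold, the protease inhibitor gene Spint2 8.42-fold and the inhibitory receptor gene Btla 7.01-fold higher. In the CD103+ DC list, 15 of 16 were higher and 1 lower, with the same counts adjusted over the list alone (camera adjusted p = 7.1e-11). This list was not called between CD14hi moDC and CD14lo cDC (3 higher and 5 lower, 3 and 6 adjusted over the list alone, camera adjusted p = 0.52). The CD11b+ DC list was not called for the lineage, with 6 of 14 higher and 4 lower (7 and 4 adjusted over the list alone, camera adjusted p = 0.77) and a median of 0.30 and mean of -0.13 on the log2 scale. All 21 tested genes of the monocyte and macrophage core were lower in the cDC, also when adjusted over the list alone (camera adjusted p = 1.8e-18). Among them were the fractalkine receptor gene Cx3cr1 (11.4-fold), the cholesterol exporter gene Abca1 (10.9-fold) and Adgre1, which encodes F4/80 (10.7-fold). The genes Dpp4 (CD26, a surface peptidase) and C5ar1 (CD88, the receptor for complement fragment C5a) are the markers that the study is known to have put forward for these lineages, so their values are not independent evidence here. Dpp4 had signals of 4821 ± 505, 3794 ± 121, 1444 ± 439 and 339 ± 50.4 in CD103+ cDC, CD14lo cDC, CD14hi moDC and Ly6Chi moDC (SD, n = 3 each) and was 5.76-fold higher in the cDC (adjusted p = 1.5e-11). C5ar1 had 815 ± 471, 2609 ± 809, 15194 ± 1286 and 13294 ± 927 in the same order and was 10.2-fold lower in the cDC (adjusted p = 7.7e-10).

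**Figure D1:**
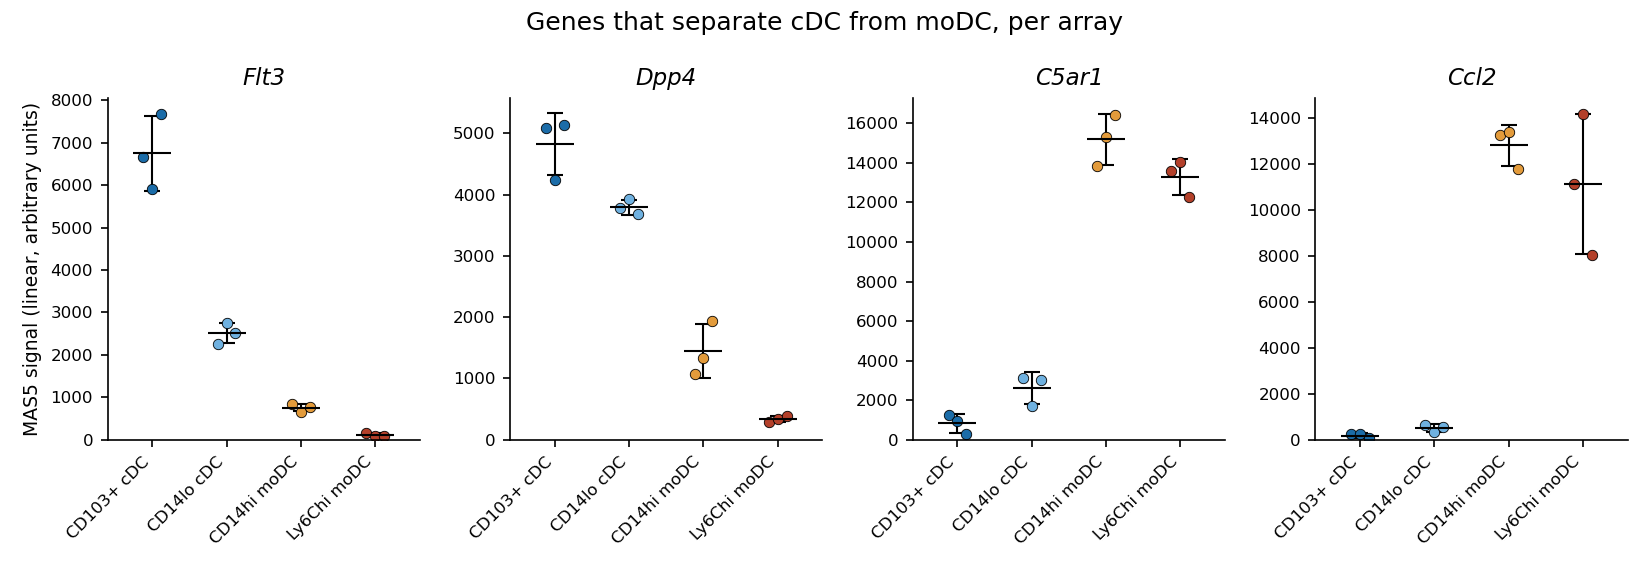
MAS5 signal (linear scale, arbitrary units) of Flt3, Dpp4, C5ar1 and Ccl2 in the 4 populations, with a point per array, a horizontal line at the mean of 3 arrays and bars of 1 SD. Mean Flt3 ran from 6749 in CD103+ cDC to 113 in Ly6Chi moDC, and mean Ccl2 was 175 and 498 in the cDC against 12804 and 11102 in the moDC.

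Chemokine genes were lower in the cDC for 16 of 22 and higher for 3 (17 and 3 adjusted over the list alone, camera adjusted p = 2.7e-09, adjusted p = 0.086 with an estimated correlation). Of 18 cytokine genes, 14 were lower and 2 higher, with the same counts adjusted over the list alone (camera adjusted p = 3.8e-06, adjusted p = 0.094 with an estimated correlation). Il10, the gene of an anti-inflammatory cytokine, was 5.65-fold lower, the cyclooxygenase gene Ptgs2 6.32-fold lower, and Il12b, which encodes the p40 chain of interleukin 12, 6.84-fold higher in the cDC. Every tested complement gene, 11 of 11, was lower in the cDC, also when adjusted over the list alone (camera adjusted p = 3.6e-10). Of 21 pattern recognition receptor genes 19 were lower and 1 higher (19 and 1 adjusted over the list alone, camera adjusted p = 2.9e-10), led by the C-type lectin genes Clec4d (14.7-fold), Clec4e (12.4-fold) and Clec4n (11.6-fold). Scavenger receptor genes were lower for 10 of 16 and higher for 1 (10 and 1 adjusted over the list alone, camera adjusted p = 5.2e-06). Msr1 was 16.1-fold lower and Timd4, a receptor for phosphatidylserine on dying cells, 7.95-fold higher in the cDC. Lysosomal genes were lower for 13 of 18 (13 adjusted over the list alone, camera adjusted p = 2.1e-07, adjusted p = 0.061 with an estimated correlation), including the cathepsin gene Ctsd (6.04-fold). Interferon-stimulated genes were lower for 15 of 21 (15 lower and 1 higher adjusted over the list alone, camera adjusted p = 6.5e-06, adjusted p = 0.15 with an estimated correlation), with Cxcl10 3.35-fold and Cmpk2 2.70-fold lower. Between CD14hi moDC and CD14lo cDC the same list was not called, with 2 higher and 1 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.69).

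Genes of costimulation and DC maturation were higher in the cDC for 17 of 18 (18 adjusted over the list alone, camera adjusted p = 6.9e-11, adjusted p = 0.068 with an estimated correlation). Their largest differences, in Cd200 (6.08-fold), the lymph node homing receptor gene Ccr7 (5.47-fold), Ccl22 (5.01-fold) and the actin bundling gene Fscn1 (4.31-fold), rested on the low values of Ly6Chi moDC: mean Ccr7 was 27133, 14474, 14561 and 936 from CD103+ cDC to Ly6Chi moDC. Cell cycle genes were higher for 22 of 25, as many when adjusted over the list alone (camera adjusted p = 6.8e-09), with the nucleotide reductase gene Rrm2 3.17-fold and the proliferation marker Mki67 2.87-fold higher. Between CD14hi moDC and CD14lo cDC the cell cycle list was not called (mean log2 difference -0.03, camera adjusted p = 0.83). Maturation genes were not called there either (1 of 18 lower, 1 adjusted over the list alone, camera adjusted p = 0.37), but were without CD14lo cDC replicate 2 (adjusted p = 0.048) or CD14hi moDC replicate 3 (0.038). Some markers of other cells also differed in this averaged comparison, but not all followed the division. From CD103+ cDC to Ly6Chi moDC, mean S100a8 was 355, 259, 401 and 1257, and mean Sftpc 851, 173, 407 and 171. Of 4 tested neutrophil markers 3 were lower in the cDC (4 adjusted over the list alone), led by Csf3r at 5.51-fold, too few for a list test. NK cell markers were higher in the cDC for 4 of 5, as many when adjusted over the list alone (camera adjusted p = 0.0032, adjusted p = 0.068 with an estimated correlation), led by Klrd1 at 5.50-fold. Only markers that passed the signal filter were tested. The NK cell markers Ncr1, Nkg7, Eomes and Gzmb did not pass it, with means of at most 26.5 in every population. Fibroblast markers were lower for 4 of 6, as many when adjusted over the list alone (camera adjusted p = 0.020, adjusted p = 0.088 with an estimated correlation), led by Mgp at 2.78-fold. Lung epithelium markers were higher for 5 of 9, as many when adjusted over the list alone (camera adjusted p = 0.032, adjusted p = 0.19 with an estimated correlation). This call was lost without CD103+ cDC replicate 1 (adjusted p = 0.055).

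The second comparison was between the CD11bhi populations that CD14 separates, CD14hi moDC and CD14lo cDC. CD14hi moDC carried large amounts of chemokine message that was low in CD14lo cDC: Cxcl13, the gene of a B cell attractant, had 10162 ± 3322 against 161 ± 119.9, and Pf4, Ccl7 and Ccl12 were 50.7-fold, 49.9-fold and 49.4-fold higher. The growth factor gene Igf1 was 39.2-fold higher (log2 difference 5.29 ± 0.21, adjusted p = 9.9e-12) and Olfml3 30.2-fold higher. In the other direction, CD14lo cDC held more of Cd7 (25.9-fold, log2 difference -4.70 ± 0.27), the short-chain fatty acid receptor gene Ffar2 (12.7-fold), Bex6 (7.44-fold), the lectin-like receptor gene Klra17 (7.41-fold), the lectin gene Clec10a (6.83-fold) and Cdh1, which encodes E-cadherin (6.46-fold). In this comparison 1012 genes were higher and 768 lower in CD14hi moDC, 16.3% of those tested, with 519 and 238 at 2-fold or more. Without CD14hi moDC replicate 1 the count of lower genes was 511. With each array centred at its median, where the median log2 difference of all genes was -0.11, the counts were 793 higher and 950 lower, so which direction held more genes depended on the scaling.

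The monocyte and macrophage core was higher in CD14hi moDC for 19 of 21 genes (20 adjusted over the list alone, camera adjusted p = 9.8e-18), with Adgre1 9.16-fold and the engulfment receptor gene Mertk 7.29-fold higher. Cd14 itself, which the sort selected on, was 7.34-fold higher, at 11669 ± 2479.7 against 1537 ± 245. C5ar1 was 5.93-fold higher (adjusted p = 1.2e-05) and Dpp4 2.65-fold lower (adjusted p = 1.5e-05). The conventional DC core was lower for 10 of 13 genes and higher for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 1.7e-10). The transcription factor gene Bcl11a was 6.39-fold, the tryptophan pathway gene Kmo 5.55-fold, Kit 4.62-fold and Flt3 3.19-fold lower. Chemokine genes were higher for 18 of 22 and lower for 1, with the same counts adjusted over the list alone (camera adjusted p = 4.4e-19). Of 18 cytokine genes 8 were higher, as many when adjusted over the list alone (camera adjusted p = 3.1e-05, adjusted p = 0.14 with an estimated correlation): Il10 was 5.26-fold, Tnf 5.13-fold, Il1a 4.35-fold and Il6 3.75-fold higher.

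Complement genes were higher in CD14hi moDC for 8 of 11 (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.0e-07, adjusted p = 0.055 with an estimated correlation). C1qa was 18.7-fold and the C3a receptor gene C3ar1 12.8-fold higher. Scavenger receptor genes were higher for 9 of 16 and lower for 2 (11 and 3 adjusted over the list alone, camera adjusted p = 4.4e-06), with Trem2 11.8-fold and Cd36 7.80-fold higher. For pattern recognition receptors the counts were 10 higher and 1 lower of 21 (13 and 2 adjusted over the list alone, camera adjusted p = 8.2e-06). Lysosomal genes were higher for 11 of 18 (15 adjusted over the list alone, camera adjusted p = 1.7e-08), with the cathepsin genes Ctsl 3.38-fold and Ctsd 2.89-fold higher. Alveolar macrophage markers were not called (2 of 11 higher, 2 adjusted over the list alone, camera adjusted p = 0.46), but were higher without CD14lo cDC replicate 1 (mean log2 difference 0.64 against 0.21, adjusted p = 0.013). Their spread was wide in CD14lo cDC, with Chil3 at 1642 ± 1993. Fibroblast markers were higher in CD14hi moDC for 5 of 6, as many when adjusted over the list alone (camera adjusted p = 1.4e-04), and Mgp reached 4067 ± 519 against 1135 ± 285. NK cell markers were lower for 3 of 5, as many when adjusted over the list alone (camera adjusted p = 7.1e-05), and Klrd1 had 1036 ± 309 against 6418 ± 383. The NK cell markers Ncr1, Nkg7, Eomes and Gzmb were dim in both populations and were not tested.

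Next, the conventional populations were compared with each other. CD103+ cDC were set apart by Xcr1, the receptor for a chemokine of T and NK cells (2656 ± 744 against 94.8 ± 41.2, 18.7-fold higher, log2 difference 4.23 ± 0.24). Also higher were the peptidase gene Naalad2 (31.3-fold), Itgae (17.7-fold), Gcsam (16.4-fold), Gpr33 (16.2-fold) and Ttc39a (15.4-fold). CD14lo cDC held more of the collagen receptor gene Ddr1, 38.6-fold lower in CD103+ cDC (log2 difference -5.27 ± 0.24), and of Ifitm6 (34.5-fold lower) and the C-type lectin genes Clec10a (31.0-fold), Cd209c (30.1-fold), Clec4a3 (28.6-fold) and Cd209a (26.9-fold). In all, 1465 genes were higher and 1674 lower in CD103+ cDC (28.7% of those tested), 542 and 630 of them by at least 2-fold. The counts were 715 and 761 with the bioB signal as a covariate. That signal ran from 5446 to 7837 in CD103+ cDC and from 2699 to 3551 in CD14lo cDC, without overlap. The covariate thus follows the comparison itself, and the lower counts cannot show a technical cause. A fit without CD103+ cDC replicates 1 and 3, which had the highest Gapdh ratios, leaves a lone array there and is described with the processing alternatives. The CD103+ cDC arrays also had the highest mean Gapdh 3' to 5' ratio, 2.74 ± 0.91 against 1.85 ± 0.39 (SD, n = 3). Itgam, which encodes CD11b, was 11.6-fold lower in CD103+ cDC, a difference that the sort itself selected, and C5ar1 was 3.39-fold lower. Cd14 was called lower too (log2 difference -0.71). That call was lost with quantile normalization (adjusted p = 0.055) and without CD103+ cDC replicate 2 (0.15), among other settings. Dpp4 was not called (log2 difference 0.34 ± 0.18, adjusted p = 0.18), although the mean of its probe sets was (log2 difference 0.43, adjusted p = 0.028).

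The CD103+ DC list was higher in CD103+ cDC for 15 of 16 genes, as many when adjusted over the list alone (camera adjusted p = 1.3e-19), including the adhesion gene Cadm1 (12.9-fold). Conventional DC core genes were higher for 9 of 13 and lower for 2, with the same counts adjusted over the list alone. Their camera adjusted p was 0.0015, 0.13 with an estimated correlation and 0.059 with the bioB signal as a covariate. The CD11b+ DC list was lower for 10 of 14 and higher for 2 (10 and 4 adjusted over the list alone, camera adjusted p = 5.5e-06, adjusted p = 0.067 with an estimated correlation). Sirpa, the gene of an inhibitory receptor, was 25.5-fold and the transcription factor gene Zeb2 15.5-fold lower. The monocyte and macrophage core was lower for 15 of 21 (16 adjusted over the list alone, camera adjusted p = 7.0e-10), with Fcgr1, which encodes CD64, 11.6-fold and Csf1r, the receptor for a macrophage growth factor, 9.13-fold lower. Fc receptor genes were lower for 5 of 6, as many when adjusted over the list alone (camera adjusted p = 1.6e-06, adjusted p = 0.067 with an estimated correlation). Complement genes were lower for 9 of 11, as many when adjusted over the list alone (camera adjusted p = 2.2e-07, adjusted p = 0.067 with an estimated correlation), with C1qb 8.02-fold lower. Pattern recognition receptor genes divided: 16 of 21 were lower and 3 higher (17 and 3 adjusted over the list alone, camera adjusted p = 1.8e-05, adjusted p = 0.067 with an estimated correlation). Tlr3, a sensor of double-stranded RNA, was 8.70-fold higher and Clec4n 14.3-fold lower. Interferon-stimulated genes were lower for 11 of 21 and higher for 1 (13 and 2 adjusted over the list alone, camera adjusted p = 1.2e-04, adjusted p = 0.23 with an estimated correlation), with Oas2 4.25-fold lower and Oasl1 2.69-fold higher.

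Maturation genes were higher in CD103+ cDC for 13 of 18 (14 adjusted over the list alone, camera adjusted p = 1.3e-06, adjusted p = 0.19 with an estimated correlation). The costimulatory gene Cd86 was 2.67-fold higher, at 8070.5 ± 1587 against 2978 ± 533. Cell cycle genes were higher for 13 of 25 (16 adjusted over the list alone, camera adjusted p = 3.7e-07, adjusted p = 0.067 with an estimated correlation), with Rrm2 3.10-fold and the cyclin gene Ccna2 3.00-fold higher. Class I presentation genes were higher for 10 of 15, as many when adjusted over the list alone (camera adjusted p = 5.7e-04, adjusted p = 0.23 with an estimated correlation), with the transactivator gene Nlrc5 2.00-fold higher. With the bioB control signal as a covariate this call was lost (adjusted p = 0.26). Of 12 class II presentation genes 2 were higher and 3 lower (3 and 3 adjusted over the list alone). The median and mean differed in sign (0.07 and -0.07 on the log2 scale) and the list was not called (camera adjusted p = 0.99). After quantile normalization its mean became -0.34 (adjusted p = 0.0056). Ciita, the master regulator of class II genes, was 2.13-fold lower in CD103+ cDC. Lung epithelium markers were higher for 6 of 9 and lower for 1, with the same counts adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.21 with an estimated correlation). Epcam was 4.03-fold and the surfactant gene Sftpc 4.01-fold higher, and Cdh1 14.4-fold lower. Leaving out CD103+ cDC replicate 1 ended that call (adjusted p = 0.0502).

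The last planned contrast set Ly6Chi moDC against CD14hi moDC. Ly6Chi moDC carried more of Arg1, the gene of an enzyme that breaks down arginine (3108 ± 308 against 169 ± 98.4, 15.3-fold, log2 difference 3.93 ± 0.29). Also higher were Ly6i (10.1-fold), the matrix gene Thbs1 (9.13-fold), the chitinase-like gene Chil3 (7.73-fold), Plac8 (7.10-fold) and Cd177 (7.07-fold). CD14hi moDC carried 46.6-fold more Cxcl13, 34.6-fold more Mucl1, 28.2-fold more Aldh1a2, which encodes an enzyme of retinoic acid synthesis, 26.1-fold more Serpinb6b, 25.7-fold more Retnla and 25.7-fold more Ccl22, the gene of a chemokine. Aldh1a2 had 5042 ± 519 in CD14hi moDC and 130.2 ± 10.2 in Ly6Chi moDC (adjusted p = 2.0e-13), and 4475 ± 338 and 3069.9 ± 558 in CD103+ cDC and CD14lo cDC. In this contrast 743 genes were higher and 1245 lower in Ly6Chi moDC, 18.2% of those tested, with 195 and 644 at 2-fold or more. Median centring, where the median log2 difference of all genes was 0.21, gave 1866 higher and 827 lower, so which direction held more genes depended on the scaling. The higher count was 492 without Ly6Chi moDC replicate 3 and 476 with the bioB covariate.

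The inflammatory monocyte list was higher in Ly6Chi moDC for 12 of 15 genes (13 adjusted over the list alone, camera adjusted p = 7.5e-13), among them the matrix proteoglycan gene Vcan (5.74-fold). Interferon-stimulated genes were higher for 15 of 21 (16 adjusted over the list alone, camera adjusted p = 1.8e-10, adjusted p = 0.14 with an estimated correlation), with Ifi204 2.40-fold and the RNA sensor gene Ddx58 2.23-fold higher. Maturation genes were lower for 12 of 18 (14 adjusted over the list alone, camera adjusted p = 6.2e-12, adjusted p = 0.14 with an estimated correlation), with Cd200 15.9-fold, Ccr7 15.8-fold and Fscn1 13.1-fold lower. Conventional DC core genes were lower for 9 of 13 and higher for 1, with the same counts adjusted over the list alone (camera adjusted p = 1.3e-08), including the transcription factor gene Zbtb46 (6.26-fold) and Flt3 (4.97-fold). Cell cycle genes were lower for 18 of 25 (20 adjusted over the list alone, camera adjusted p = 4.0e-11), with Rrm2 2.85-fold and Mcm7 2.31-fold lower. Chemokine genes were lower for 11 of 22 and higher for 3, with the same counts adjusted over the list alone (camera adjusted p = 0.0012, adjusted p = 0.55 with an estimated correlation), with Ccl8 5.04-fold and Ccl17 8.30-fold lower. The monocyte and macrophage core was not called (5 higher and 1 lower of 21, 5 and 2 adjusted over the list alone, camera adjusted p = 0.28). Dpp4 was 3.75-fold lower in Ly6Chi moDC. C5ar1 was not called (log2 difference -0.19 ± 0.32, adjusted p = 0.75), and another of its probe sets moved the other way. Neither was Cd14 (-0.10 ± 0.23, adjusted p = 0.83). Of 4 tested neutrophil markers 3 were higher in Ly6Chi moDC, as many when adjusted over the list alone, led by S100a8 at 1257 ± 264 against 401 ± 229.6. The call of S100a8 was lost without CD14hi moDC replicate 1 (adjusted p = 0.058) or 2 (0.11) and without Ly6Chi moDC replicate 1 (0.051) or 2 (0.075). Alveolar macrophage markers were lower for 4 of 11 and higher for 1 (5 and 1 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.58 with an estimated correlation). Fabp4 was 8.39-fold lower, and the higher member was Chil3. No value is given for Ly6C, since its genes share a probe set that carries several symbols.

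**Figure D2:**
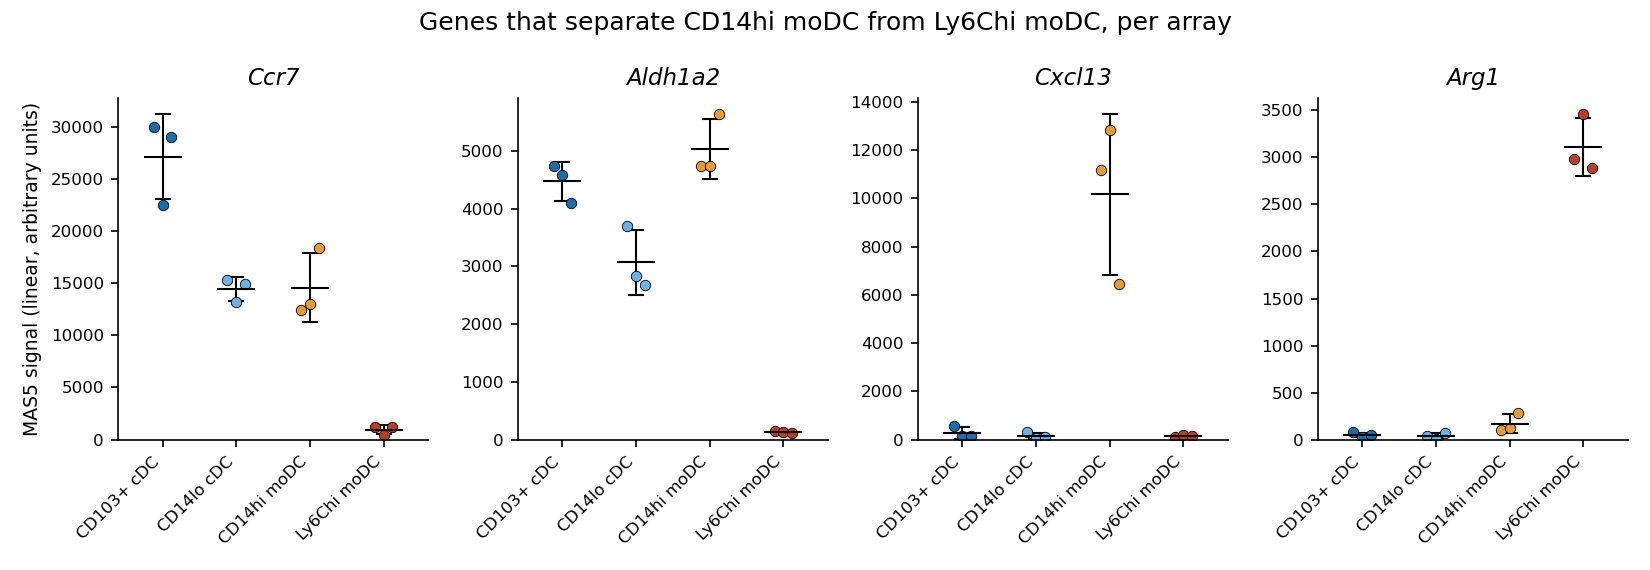
MAS5 signal (linear scale, arbitrary units) of Ccr7, Aldh1a2, Cxcl13 and Arg1 in the 4 populations, with a point per array, a horizontal line at the mean of 3 arrays and bars of 1 SD. Ly6Chi moDC had the lowest mean Ccr7 (936) and Aldh1a2 (130.2) and the highest mean Arg1 (3108), and CD14hi moDC had the highest mean Cxcl13 (10162).

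For the remaining pairs, counts, the study markers and the directions of the sort markers are given. CD103+ cDC differed from CD14hi moDC by 1851 higher and 2210 lower genes, and from Ly6Chi moDC by 2534 higher and 2657 lower genes. Median centring turned the former to 2145 higher and 1767 lower and gave 2048 and 3178 for the latter, at median log2 differences of all genes of 0.08 and -0.14. The former counts were 1082 and 1356 without CD103+ cDC replicates 1 and 3, and the latter lower count was 1759 with the bioB covariate. Ly6Chi moDC differed from CD14lo cDC by 1226 higher and 1527 lower genes, which median centring turned to 1586 higher and 1098 lower at a median log2 difference of all genes of 0.11. Dpp4 was 3.34-fold higher in CD103+ cDC than in CD14hi moDC and 12.5-fold higher than in Ly6Chi moDC, and it was 9.92-fold lower in Ly6Chi moDC than in CD14lo cDC. C5ar1 was 20.1-fold and 17.6-fold lower in CD103+ cDC than in CD14hi and Ly6Chi moDC, and 5.20-fold higher in Ly6Chi moDC than in CD14lo cDC. Of the 3 tested sort markers, Itgae was higher and Itgam and Cd14 lower in CD103+ cDC than in either moDC population. In Ly6Chi moDC, Itgae was lower and Itgam and Cd14 higher than in CD14lo cDC.

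Each population also had genes that differed in the same direction from all 3 others. CD103+ cDC had 1033 such genes on the high side and 1085 on the low side. The high side was led by Naalad2 (3404 ± 284 against at most 62.1 elsewhere), Xcr1, Itgae, Gcsam and Gpr33. The low side was led by Clec4a3, Sirpa and the receptor gene Cd300ld, with Sirpa at 245 ± 88.8 against at least 7259.6 in the others. Ly6Chi moDC had 368 and 709, with Arg1, Thbs1, Cd177, the Schlafen gene Slfn4 and the protease inhibitor gene Slpi highest, and Serpinb6b, the adenylate cyclase gene Adcy6 and Adam23 lowest. Slfn4 reached 9119 ± 329 there against at most 1501 elsewhere. CD14hi moDC had 214 and 66, with Cxcl13, the intermediate filament gene Nes (2145 ± 189 against at most 53.9), Mucl1, Speg and Tcim highest, and Gcnt2, the serine synthesis gene Phgdh and Parvg lowest. The low-side count for CD14hi moDC was 40 without CD14hi moDC replicate 1, 42 without CD14hi moDC replicate 2 and 43 without Ly6Chi moDC replicate 1. With each array centred at its median, Ly6Chi moDC had 726 and 466, and CD14hi moDC had 147 on the low side. With the bioB covariate CD103+ cDC had 558 and 537, the low-side count was 38 for CD14hi moDC, and the high-side count was 233 for Ly6Chi moDC and 99 for CD14lo cDC. Without CD103+ cDC replicates 1 and 3, CD103+ cDC had 559 and 620, and CD14lo cDC 49 on the low side. CD14lo cDC had 149 and 75, with Cd7 (1786 ± 576 against at most 148), Ffar2, Klra17, Clec10a and the interferon-induced membrane gene Ifitm1 highest, and Rab7b, Bst1 and Igf2r lowest. Even the smallest of the 3 differences was 31.3-fold for Naalad2, 35.8-fold for Cxcl13, 15.3-fold for Arg1 and 9.29-fold for Cd7.

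**Figure D3:**
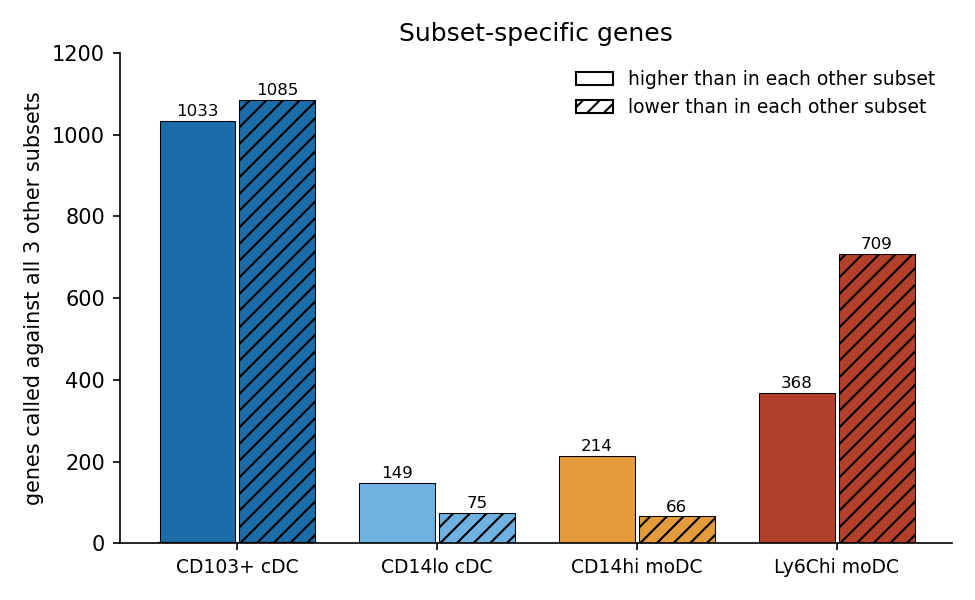
Number of genes called higher (plain bars) or lower (hatched bars) in a population than in each of the 3 others, with no error bars because each bar is a count. CD103+ cDC had 1033 and 1085, CD14lo cDC 149 and 75, CD14hi moDC 214 and 66, and Ly6Chi moDC 368 and 709.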

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

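The bioB covariate, the Gapdh ratio covariate and the fit without both CD103+ cDC arrays of highest Gapdh ratio were tests chosen after the data were seen. Of 592 counts under the alternatives, 520 were within 1.5 times the main count and 72 were not. Of 10346 values of named genes 9980 kept direction and call, 357 lost the call, 7 gained it and 2 reversed, and of 2455 list values 2362 kept both, 44 lost the call, 47 gained it and 2 reversed. Every reversal was in CD103+ cDC against CD14lo cDC, and for lists it was of the direction given by camera, not of the mean. Cd74 went from 0.57 on the log2 scale to -0.024 with quantile normalization and -0.10 with the bioB covariate, uncalled in both. The mean of the class II presentation list, -0.07 and uncalled in the main fit, went to -0.34 and -0.50 (camera adjusted p = 0.0056 and 2.8e-04). Its mean thus kept its sign and the list gained a call. The cause was not tested. In the pairs that follow, the number of higher genes comes first. A 2-fold requirement, which can only remove calls, gave 561 and 623 for the lineage comparison, 519 and 238 for CD14hi moDC against CD14lo cDC, 542 and 630 for CD103+ cDC against CD14lo cDC, 195 and 644 for Ly6Chi moDC against CD14hi moDC, 716 and 979 for CD103+ cDC against CD14hi moDC, 1289 and 1128 for CD103+ cDC against Ly6Chi moDC and 494 and 693 for Ly6Chi moDC against CD14lo cDC. Specific genes numbered 398 and 397 for CD103+ cDC, 51 and 15 for CD14lo cDC, 115 and 10 for CD14hi moDC and 97 and 329 for Ly6Chi moDC. Testing every probe set, which tests more features, gave 4660 and 4339 for the lineage comparison, 1838 and 1319 for CD14hi moDC against CD14lo cDC, 2838 and 3174 for CD103+ cDC against CD14lo cDC, 1285 and 2626 for Ly6Chi moDC against CD14hi moDC, 3632 and 4365 for CD103+ cDC against CD14hi moDC, 5462 and 5131 for CD103+ cDC against Ly6Chi moDC and 2178 and 3098 for Ly6Chi moDC against CD14lo cDC. Specific genes numbered 1981 and 2013 for CD103+ cDC, 235 higher for CD14lo cDC, 390 and 109 for CD14hi moDC and 621 and 1429 for Ly6Chi moDC. The filter at the 75th percentile, which tests fewer genes, gave 643 higher for CD14hi moDC against CD14lo cDC and 787 lower for Ly6Chi moDC against CD14hi moDC. Specific genes numbered 99 higher for CD14hi moDC. Median centring gave 1866 and 827 for Ly6Chi moDC against CD14hi moDC. Specific genes numbered 147 lower for CD14hi moDC and 726 and 466 for Ly6Chi moDC. The bioB covariate gave 715 and 761 for CD103+ cDC against CD14lo cDC, 476 higher for Ly6Chi moDC against CD14hi moDC and 1759 lower for CD103+ cDC against Ly6Chi moDC. Specific genes numbered 558 and 537 for CD103+ cDC, 99 higher for CD14lo cDC, 38 lower for CD14hi moDC and 233 higher for Ly6Chi moDC. Without both CD103+ cDC arrays of highest Gapdh ratio, which leaves that population a lone array assumed to vary like the others, the counts were 764 and 953 for CD103+ cDC against CD14lo cDC and 1082 and 1356 for CD103+ cDC against CD14hi moDC. Specific genes numbered 559 and 620 for CD103+ cDC and 49 lower for CD14lo cDC. For median centring and the bioB covariate the cause was not tested. Leaving out each array in turn gave 511 to 809 lower genes in CD14hi moDC against CD14lo cDC, lowest without CD14hi moDC replicate 1. It gave 492 to 798 higher genes in Ly6Chi moDC against CD14hi moDC, lowest without Ly6Chi moDC replicate 3, and 40 to 74 genes specific to CD14hi moDC on the low side, lowest without CD14hi moDC replicate 1. The cause was not tested beyond the fewer arrays. With replicate number as a block the lineage counts were 2303 and 2307, and none of the 22 counts moved by over 1.5 times. Nothing in the labels ties arrays of a number together, and they were not treated as pairs, since not every such pair correlated above 0.1. Pairs of arrays sharing a number had a mean residual correlation across genes of 0.0625, from -0.103 to 0.233, against -0.0313, from -0.264 to 0.234, for the other pairs, and genes are not independent replicates. Of the former 8 of 18 were above 0.1 and of the latter 4 of 36, and all but CD14lo cDC replicate 2 and Ly6Chi moDC replicate 3 correlated best with an array of their own number, a hint from the data that some arrays of a number deviated together. Signal over background limits the dim genes, since from 55.4% to 61.7% of probe sets on an array exceeded the pseudocount.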

Other observations

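The Epcam test, the groupings of whole populations other than by lineage, the leave-one-out spread of the covariate counts and the choice of Cadm1, Cd36, Cd7, Ffar2, Cdh1 and the keratin genes as examples were made after the values were seen. Some genes joined CD103+ cDC with CD14hi moDC instead of following the lineage. Mean Cd36, a scavenger receptor gene, was 7544 in CD103+ cDC and 7408 in CD14hi moDC but 923 in CD14lo cDC and 990.1 in Ly6Chi moDC, and mean Cadm1, an adhesion gene, was 3786 and 2731 against 251 and 112. Setting those populations against the other two called 3596 genes with limma, 741 of them at 2-fold or more. The lineage grouping called 4533, and CD103+ cDC with Ly6Chi moDC against the others 1609. Each grouping compares means, which a single population can move, so these are not counts of genes shared by the populations set together.

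Markers of other cells were uneven. All 6 erythroid and platelet markers on the array had a mean signal under 100 in every population, as did 7 of 8 mast cell and basophil markers, 7 of 11 neutrophil markers, 5 of 9 T cell, 5 of 9 NK cell and 4 of 9 B cell markers. The highest mean signal of a marker in any population was 6685 for alveolar macrophages (Chil3), 6418 for NK cells (Klrd1), 4857 for lung epithelium (Scgb1a1), 4067 for fibroblasts (Mgp) and 3782 for T cells (Il7r). It was 2079 for plasmacytoid DC (Tcf4), 1533 for neutrophils (Csf3r), 1377 for B cells (Ighm) and 689 for endothelium (Kdr).

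Regroupings of the arrays were counted with the real one included. For the lineage comparison, 1 of 100 random relabellings called as many genes as the real 4533, the real one itself, and the highest other called 635. These draws mixed arrays of different populations, so they show that the populations differ and do not test the lineage division itself. Whole populations can be paired in too few ways for a share under 0.05, and the other pairings called 3596 and 1609 genes. Each pair of populations allows only 10 splits of its 6 arrays, too few for a share under 0.05. In each pair 1 of 10 splits called as many genes as the real one, and the highest other called 0 genes with limma. The real counts were 1780 for CD14hi moDC against CD14lo cDC, 3139 for CD103+ cDC against CD14lo cDC, 1988 for Ly6Chi moDC against CD14hi moDC, 4061 for CD103+ cDC against CD14hi moDC, 5191 for CD103+ cDC against Ly6Chi moDC and 2753 for Ly6Chi moDC against CD14lo cDC. At an unadjusted p under 0.05 the highest other splits held, in that order, 893, 1072, 574, 888, 802 and 590 genes. As many specific genes arose in 1 of 100 relabellings for CD103+ cDC (2118, highest other 51) and 3 of 100 for CD14lo cDC (224, highest other 1190). The shares were 4 of 100 for CD14hi moDC (280, highest other 1262) and 1 of 100 for Ly6Chi moDC (1077, highest other 0 with limma, 415 at an unadjusted p under 0.05). Since the draws mixed populations, these shares show that arrays of a population resemble each other, and they say nothing more about the size of each count. The larger relabellings put the name CD14lo cDC or CD14hi moDC on all 3 arrays of CD103+ cDC or of Ly6Chi moDC, which points to a structure of the samples, the larger distance of those populations from the others.

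CD103+ cDC held the most specific genes, 2118 against 1077 in Ly6Chi moDC, and also had the highest Gapdh 3' to 5' ratio, although their beta-actin ratio, 1.04 ± 0.08, was close to the 1.03 ± 0.03 of Ly6Chi moDC (SD, n = 3). With the bioB signal as a covariate the counts were 1095 and 777, and with the Gapdh ratio as a covariate 1465 and 1130, so CD103+ cDC stayed highest, which was the outcome set down as speaking against either technical cause. That criterion left out the spread of the counts: with an array left out in turn, CD103+ cDC counts ran from 503 to 1159 and from 478 to 1559, Ly6Chi moDC counts from 445 to 816 and from 767 to 1239, and CD103+ cDC were highest in 11 of 12 runs with either covariate. Without both CD103+ cDC arrays of highest Gapdh ratio the counts were 1179 and 1121. The median size of a log2 difference from the other populations was 0.37 in CD103+ cDC without a covariate, 0.40 with bioB and 0.37 with the Gapdh ratio, against 0.32, 0.33 and 0.33 in Ly6Chi moDC. Array brightness, whatever raised the Gapdh ratio and a biological distance of CD103+ cDC may each contribute. They cannot be told apart because both covariates largely followed the population. The bioB signal was 7140, 5446 and 7837 in CD103+ cDC, and elsewhere only CD14hi moDC replicate 3 (8366) exceeded the lowest of these. The Gapdh ratio was 3.26, 1.68 and 3.27 in CD103+ cDC and at most 2.29 elsewhere. The ranges of the counts also overlapped, and such counts depend on precision as well as on effect size.

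Epcam and Cldn1, genes also found in epithelium, were far higher in CD103+ cDC than in CD14hi moDC, and epithelial RNA in the sort could be a source. Their median log2 difference was 4.28, against 1.11 for 5 surfactant and secretoglobin genes, a gap of 3.17 (SE 0.27). One source adds its genes in 1 ratio, but a log2 difference also depends on the starting level. In CD14hi moDC the geometric means ran from 57.3 for Sftpd to 2326 for Scgb1a1, with Epcam at 154 and Cldn1 at 347. Against CD14lo cDC the rise of Epcam (mean 2526 against 598) lay within the range of the 5 genes. It was smaller than for Sftpc (851 against 173) and Sftpd (153 against 22.7). It was larger than for Sftpa1 (354 against 103), Sftpb (241 against 84.2) and Scgb1a1 (4857 against 2659). The gap therefore cannot decide whether RNA of cells rich in surfactant or secretoglobin explains Epcam and Cldn1. Such RNA is open for the surfactant genes too. The epithelial genes Krt8, Krt18 and Krt19 were dim, at 38.5 ± 26.9, 99.2 ± 39.6 and 106 ± 56.4 in CD103+ cDC (SD, n = 3). They were 13.2 ± 15.5, 61.5 ± 1.96 and 46.9 ± 16.2 in CD14hi moDC, and Krt19 was 103 ± 70.0 in CD14lo cDC. Krt8 and Krt18 did not pass the signal filter, so these values near the floor give no clear direction. Mean Cdh1 was 125 in CD103+ cDC against 349 in CD14hi moDC and 2470.3 in CD14lo cDC. These values do not settle whether epithelial cells that lack surfactant and secretoglobin were present. Expression by CD103+ cDC and epithelial RNA both remain candidate explanations.

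Most conventional DC core genes in CD14hi moDC lay between CD14lo cDC and Ly6Chi moDC. CD14lo cDC within the sort could give this, up to the stated impurity of 7%. The share of the CD14lo cDC excess over Ly6Chi moDC that CD14hi moDC held was taken for 12 genes, the study marker Dpp4 among them. These were the core genes called lower in Ly6Chi moDC than in CD14lo cDC. The median share was 30.0% (SE 8.33, from resampling the genes, which are not independent). For 9 of 12 genes it lay above 7%, which argues against an impurity of the stated size as the only source. The shares ran from -3.42% for Kmo to 101% for Ccr7 and 280.1% for Adam19, whereas an admixture would give each gene a like share. Expression of part of the core by CD14hi moDC is a candidate explanation. A larger admixture of CD14lo cDC would bring their other abundant transcripts too, but mean Cd7 was 19.6 in CD14hi moDC against 1786 in CD14lo cDC and mean Ffar2 56.0 against 1267, and the core genes Bcl11a and Kit held 3.67% and 6.01% of the excess. These values argue against an admixture near the median share.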
